A study of Mus musculus with 10 samples.

How the data were processed

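Poly(A) RNA of small intestinal crypts from 10 mice, 5 per group, was sequenced as strand-specific libraries. The deposited values were raw counts per Ensembl gene, whole numbers with no normalization, made by the authors from the reads. The submitters' processing notes name bcl2fastq 2.19.1, GSNAP, featureCounts 1.6.3 and the build mm10; the strand setting, read length and filters of the counting are not given in the sources used here. Reads that fit several copies of a gene may have been dropped or assigned to either copy, which affects pseudogenes and gene families. PCR copies cannot be recognised in counts per gene, so counting floors cover counting error only.

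The count table named the group of each column and a replicate number, but not which labelled sample it was. Columns were used as replicates of their group, numbers serve only as names of libraries, and no library was paired with another. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 19.2 to 129), so none was treated as a copy of another. Gene coordinates are those of the deposited table, and 52056 of 53801 gene rows had the same position in GENCODE M21. Symbols were found for 53620 gene IDs; a symbol shared by several IDs stayed with the ID with most counts. The 92 spike-in rows held 7 counts in all and were left out.

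Genes were tested in R 4.3.3 with edgeR 4.0.16, with TMM factors, filterByExpr (minimum count 10, minimum total count 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05 over 15993 genes; 37808 genes with too few counts were not tested. CPM are counts divided by the library total times its TMM factor, on the usual CPM scale. SE is the log2 fold change divided by the root of the F statistic. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1), on log2 CPM with a prior count of 2, and needed 3 tested members. Single values were compared by exact two-sided permutation over all 252 assignments. Pseudogene relatives were searched with BLAST 2.17.0 in the transcripts of GENCODE M21. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

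The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes Setdb1; up to 10 genes per direction with the largest change among those past the threshold, without overlap between groups and with a mean of at least 1 CPM, at most 3 of them with predicted names; in each list up to 3 members past the threshold or, where none passed, the 2 most abundant; and the genes detected only in the knockout. All genes the rule gave are named, except 1 that is not reported here. A narrower selection made after the values were seen was discarded, because it had left out a gene whose sign changed between settings. Genes outside the rule are said to have been chosen after their values were seen.

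The alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, voom with and without sample quality weights, no filter on low counts, a filter of 1 CPM in 5 libraries, leaving out mitochondrial and the 50 most abundant genes, 1 surrogate variable (sva 3.50.0), a test against a fold of 1.5, other list tests and count limits, and each library left out in turn. The direction of a list was taken from the sign of its median, a choice made after the first results were seen. Settings added after seeing the data were Xist as covariate without knockout replicate 2, and the removal of distal chromosome 6, Esr1 and Gm13394. The steps were tested on simulated counts for the 15993 genes of this comparison: 76% of genes changed 2-fold and 90% of genes changed 4-fold were recovered, with 8 false calls among 185. The simulation changed 200 genes and a list of 30, more than were called here, and drew each gene independently. It held no variation shared between genes, so it checks the steps and does not give the power of the real comparison.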

Results

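Crypts of the distal small intestine were profiled by RNA sequencing in mice with and without an inducible deletion of Setdb1 in the intestinal epithelium. Setdb1 encodes a histone methyltransferase that places silencing marks on histone H3. The control group held 5 mice with floxed Setdb1 alleles and no Cre recombinase. The knockout group held 5 mice that also carried Villin-CreERT2, a tamoxifen-dependent Cre recombinase made in intestinal epithelial cells. All mice were 8 weeks old, received 2 injections of 1 mg tamoxifen, and were sampled on day 2 from the start of the injections. The libraries held between 19158247 and 27853124 counts in genes. CreERT2 was present in the knockout group alone, so every difference below is between mice with CreERT2 and deleted Setdb1 and mice with neither.

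The Setdb1 transcript was examined first, since it checks the group labels. Setdb1 (ENSMUSG00000015697, mm10 chromosome 3, 95323525 to 95357202, minus strand) fell from 33.1 ± 2.66 CPM in the controls to 18.3 ± 3.25 CPM in the knockouts (SD, n = 5 per group). Its log2 fold change was -0.85 (SE 0.11), with an adjusted p of 0.00557 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 5 knockout libraries lay below all 5 controls (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 can give). Knockout replicate 4 kept the highest level of its group, 23.9 CPM. The counts cover the whole gene, and exons outside the deleted part would still be counted.

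The main comparison asked which transcripts differed in crypts shortly after the loss of Setdb1. Of 15993 genes tested, 25 rose and 2 fell in the knockouts by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The genes that fell were Setdb1 and Trim30e-ps1, a pseudogene of the Trim30 family (0.81 ± 0.12 to 0.17 CPM, log2 fold change -2.21), which was chosen after its values were seen. Among the genes that rose were 4 targets of the tumour suppressor p53, 11 genes of distal chromosome 6, and Zfp791, Mbl2 and Bglap3. Esr1 was also among them, and its counts may come from the CreERT2 transgene. The fitted number depended on the method and on 1 library: DESeq2 gave 93 genes and voom with sample quality weights 58, while leaving out knockout replicate 4 gave 46, 38 higher and 8 lower. All 27 genes were among those called in each of these 3 settings.

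Of the p53 target genes, 4 rose. Ccng1, which encodes cyclin G1, rose from 77.1 ± 4.67 to 166 ± 31.6 CPM (log2 fold change 1.11, SE 0.12). Plk2, a polo-like kinase, rose from 5.75 ± 0.58 to 16.8 ± 6.41 CPM (1.55, SE 0.23). Phlda3, an inhibitor of AKT signalling, rose from 0.22 ± 0.07 to 1.47 ± 0.39 CPM (2.71, SE 0.30), and Eda2r, a receptor of the tumour necrosis factor receptor family, from 0.11 ± 0.04 to 1.02 ± 0.50 CPM (3.10, SE 0.42). Of 29 tested p53 targets these 4 rose and 25 did not pass the test over all genes, and 10 were higher and 0 lower when adjusted over the list alone. Cdkn1a and Mdm2, the best known targets, had log2 fold changes of 0.11 (SE 0.13) and 0.18 (SE 0.10) and did not pass; they and Plk2 were chosen after their values were seen. The list lay above the other genes by limma's camera test (adjusted p = 2.02e-11, adjusted p = 0.135 with an estimated correlation), and by limma's fry test its members moved on balance upwards (adjusted p = 0.0114). Its median log2 fold change was 0.18 and its mean 0.53, with 25 positive and 4 negative values. The mean is raised by a few large changes, so a broad rise of p53 targets is not shown. Plk2 lost its call, as did Trim30e-ps1, when Xist was a covariate and knockout replicate 2 was left out (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0528).

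**Figure D1:**
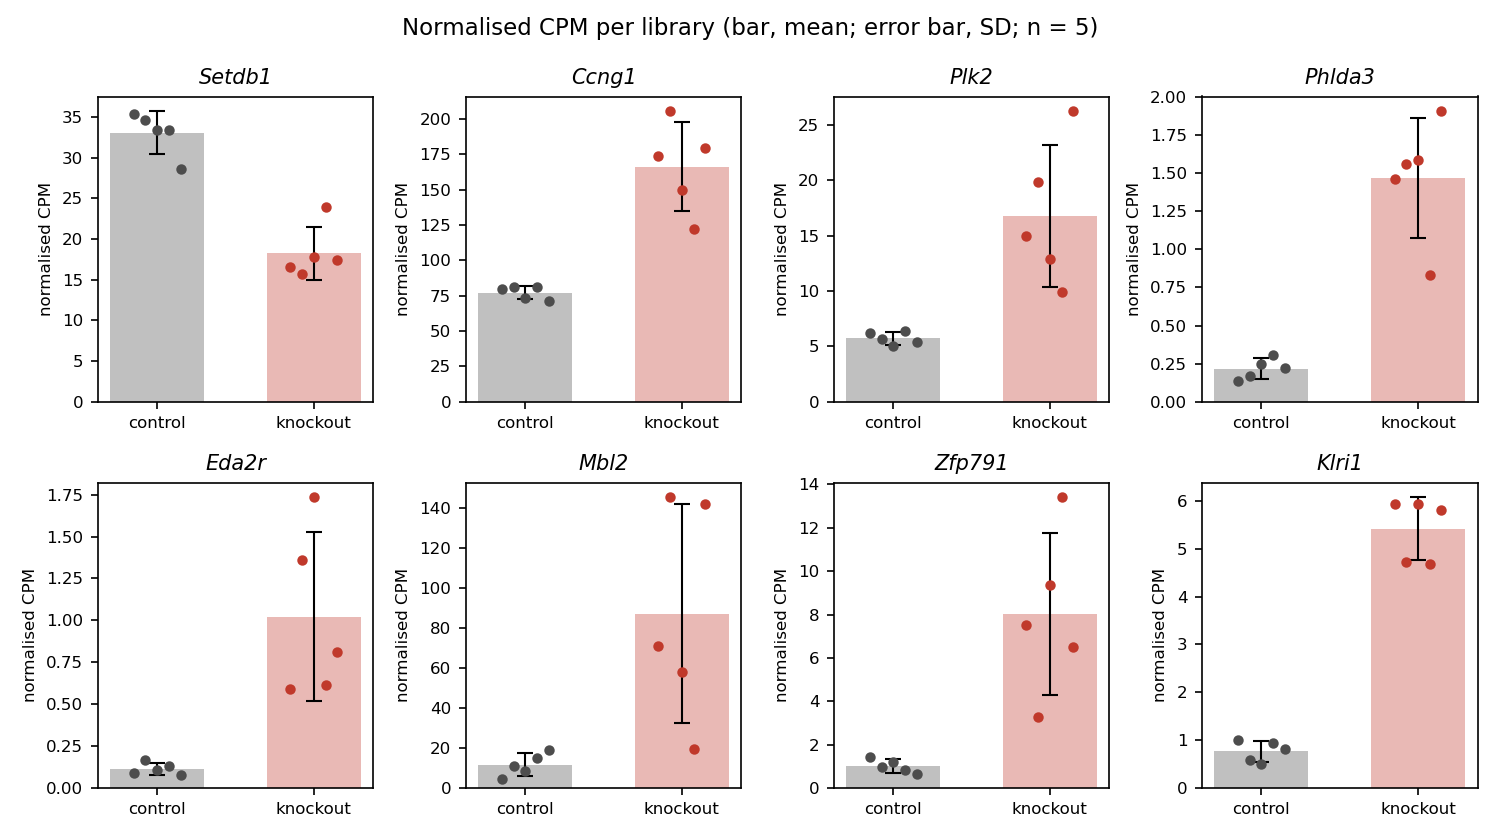
Normalised read counts (CPM) of 8 genes in the 5 control and 5 knockout libraries. Points are libraries, bars are group means and error bars are SD. Setdb1 lay lower in all 5 knockouts, and Ccng1, Plk2, Phlda3, Eda2r, Mbl2, Zfp791 and Klri1 higher.

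Many of the genes that rose lay close together on chromosome 6. Of the 27 genes past the test, 11 (40.7%) lay beyond 120 Mb on chromosome 6, between 124996694 and 149335663, against 218 (1.36%) of the 15993 genes tested (Fisher's exact test, p = 2.52e-14; the region was chosen after the values were seen). That test takes genes as independent, while Gm44135, Klri1, Klri2, Gm156 and Gm16242 are neighbours between 129696118 and 129813936. Its p therefore may overstate the gathering. Klri1 and Klri2, lectin-like receptors of natural killer cells (129697218 to 129717132 and 129729041 to 129740484), rose from 0.77 ± 0.22 to 5.42 CPM (log2 fold change 2.82, SE 0.20) and from 0.23 ± 0.08 to 2.23 CPM (3.26, SE 0.26). Pianp rose from 0.62 ± 0.16 to 3.81 CPM (2.61, SE 0.21), BC064078 from 0.78 ± 0.29 to 5.34 CPM (2.78, SE 0.28), and Gm16242 from 0.24 ± 0.17 to 1.82 CPM (2.91, SE 0.37). The remaining members, chosen after their values were seen, were Gm44216 (4.07), Gm44135 (2.40), Gm156 (1.85) and Resf1 (83.8 ± 7.09 to 147 CPM, 0.81), with log2 fold changes in parentheses, and the pseudogenes Gm45063 and Gm5154. Gm45063 (132462502 to 132462973) and Gm5154 (132438531 to 132441722) had 0 counts in the 5 controls and 187 and 64 in the knockouts, at least 69.4-fold and 23.9-fold higher when the control group is set to a floor of 3 counts. These 2 were the only genes with at most 2 counts over the controls and at least 10 in each knockout library, against 0 genes in the opposite direction, and 4 genes met looser limits of at most 5 and at least 5 counts. Several of these genes have close relatives: Gm44135 was 93.0% identical to Klri2 over its aligned part, Gm5154 92.6% to Prb1, and Gm45063 85.9% to Gm44003, so their counts are uncertain.

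**Figure D2:**
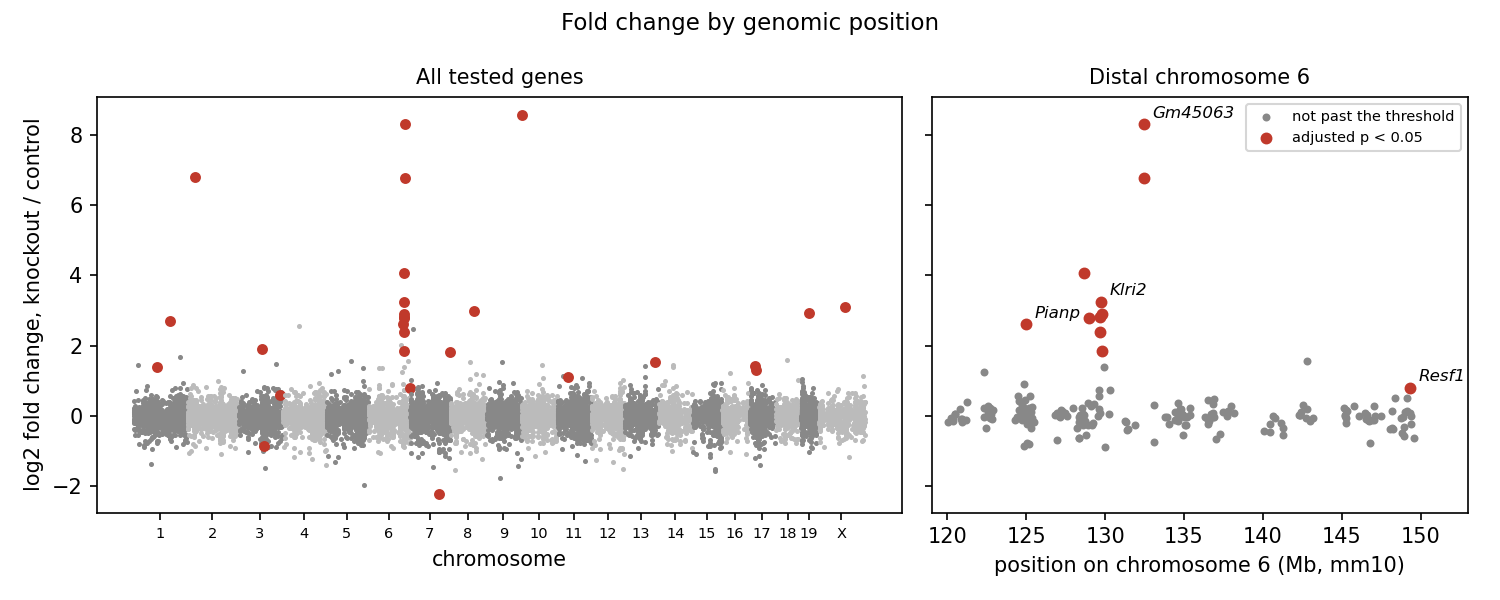
Log2 fold change of each tested autosomal and X-linked gene, knockout over control, by position along the chromosomes (left) and beyond 120 Mb on chromosome 6 in Mb of mm10 (right). Mitochondrial and Y-linked genes are not drawn. Red points are the 27 genes past an adjusted p of 0.05, 11 of them on distal chromosome 6; the fitted values of Gm45063 and Gm5154, which had 0 control counts, depend on the prior count.

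Among genes with control counts, the largest fold changes were those of Esr1 and Gm13394. Esr1, the gene of estrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), rose from 0.24 ± 0.14 to 90.1 ± 15.1 CPM (log2 fold change 8.55, SE 0.26). CreERT2 contains a ligand-binding domain of the estrogen receptor, so reads of the transgene may have been counted at Esr1. Counts per gene do not show which part of Esr1 the reads came from, so a rise of the endogenous gene is not shown. Gm13394 (chromosome 2, 28933610 to 28934609) rose from 0.40 ± 0.13 to 45.6 CPM (6.80, SE 0.24). It is a pseudogene 99.9% identical over 1000 bases to Gapdh, which lies on distal chromosome 6 (125161715 to 125166467). Other pseudogenes, such as Gm7336 on chromosome 7, were equally close to Gm13394, so reads can be shared among these genes. Gapdh itself, a glycolytic enzyme, had 10.3 ± 1.19 CPM in controls and 10.7 ± 1.59 in knockouts (SD, n = 5 per group, exact two-sided permutation p = 0.722). These values hold only the reads assigned to Gapdh, so they do not show whether its transcript changed.

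The other genes that rose lay on several chromosomes. Zfp791, a zinc finger gene, rose from 1.02 ± 0.32 to 8.01 CPM (log2 fold change 2.98, SE 0.35), and Bglap3, of the osteocalcin family, from 0.90 ± 0.12 to 3.37 CPM (1.90, SE 0.27). Mbl2, a mannose-binding lectin of innate immunity, rose from 11.5 ± 5.71 to 87.3 ± 55.0 CPM (2.91, SE 0.51). The knockouts ranged from 19.6 CPM in replicate 4 to 146 in replicate 2, and the highest control had 18.9. Further genes, chosen after their values were seen, were Tnfrsf23 (1.81), Flywch1 (1.41), Alppl2, an alkaline phosphatase (1.39), Grm4, a glutamate receptor (1.3), and Miga1, a mitochondrial fusion factor (0.61), with log2 fold changes in parentheses. Among 323 tested zinc finger genes named Zfp, Zfp791 was the only one past the test. Mbl2 kept its call in 6 of 19 settings and passed in a single leave-one-out fit, that without knockout replicate 4 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0336, highest of the others 0.311). Miga1 kept its call in 10 of 19 settings, Grm4 in 14 and Flywch1 in 17, the last losing it without knockout replicate 2 (adjusted p = 0.0634 by edgeR's test).

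Markers of T cells and intraepithelial lymphocytes did not pass singly over all genes. All 18 had positive log2 fold changes with a median of 0.48; 0 passed over all genes by edgeR, where 1160 of all tested genes had an unadjusted p under 0.05, and 16 were higher when adjusted over the list alone. Gzma, a granzyme of cytotoxic lymphocytes, stood at 432 ± 82.3 CPM in controls and 607 ± 154 in knockouts (0.49, SE 0.18), and Gzmb at 210 ± 51.7 and 282 ± 49.3 (0.42, SE 0.17). The list lay above the other genes by camera (adjusted p = 2.77e-14, adjusted p = 0.545 with an estimated correlation), and the directional fry test gave an adjusted p of 0.185. Over 13 markers of macrophages, neutrophils and mast cells the median was -0.18 and the mean 0.14, and the camera direction was up (adjusted p = 0.573). By fry's mixed test, which asks for change in either direction, their adjusted p was 1.2e-05. Adjusted over the list alone, 5 were higher, among them the mast cell protease Mcpt1 (8.32 ± 2.67 and 22.6 ± 12.2 CPM, 1.44, SE 0.35) and Tyrobp (0.70, SE 0.15; chosen after its values were seen), and 1 was lower, while Lyz2 had a value of -0.28. B cell and plasma cell markers had a median of -0.35 (adjusted p = 0.335 by camera), with Igha at -0.61 and Ighm at 0.29.

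Lists of cell division and of crypt base stem cells lay below the other genes by camera with the preset correlation only. All 24 genes of G2 and mitosis had negative log2 fold changes (median -0.54), including Mki67, a marker of dividing cells (-0.67, SE 0.34) and Top2a (-0.53, SE 0.32), and 22 of 24 S phase genes did (median -0.37; Mcm6 -0.31). All 19 stem cell markers were negative (median -0.34), with Olfm4 at -0.70 (SE 0.48) and Slc12a2 at -0.62 (SE 0.34). Medians were -0.27 for 21 DNA repair genes (Parp1 -0.30, H2afx -0.27) and -0.27 for 15 Wnt targets (Lgr4 -0.27, Ccnd1 -0.43). By camera the adjusted p was 1.79e-11 for G2 and mitosis, 9.59e-07 for S phase, 1.73e-06 for stem cells, 1.22e-05 for DNA repair and 0.00497 for Wnt targets, and with an estimated correlation the adjusted p was 0.545 for each of the 5. With 1 surrogate variable the calls of stem cells (median -0.09, adjusted p = 0.202), DNA repair (-0.04, 0.129) and Wnt targets (-0.11, 0.335) ended, and that of Wnt targets also without control replicate 2 (0.0662) or knockout replicate 1 (0.0703). Over all genes, or over each list alone, 0 members passed edgeR's test. Relative to the control mean, the G2 and mitosis list stood at -0.82, -1.72 and -1.25 (log2) in knockout replicates 1, 2 and 5 and at 0.01 and 0.18 in replicates 3 and 4, against -0.38 to 0.22 in the controls. In the same order the stem cell list stood at -0.64, -1.32 and -1.01, then 0.15 and 0.19. S phase stood at -0.42, -1.06 and -0.67, then 0.16 and -0.02. The enterocyte list, described below, ran the other way, at 0.36, 0.73 and 0.72, then -0.01 and -0.66. The same knockouts lay apart on the first principal component, so these lists are not independent results.

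**Figure D3:**
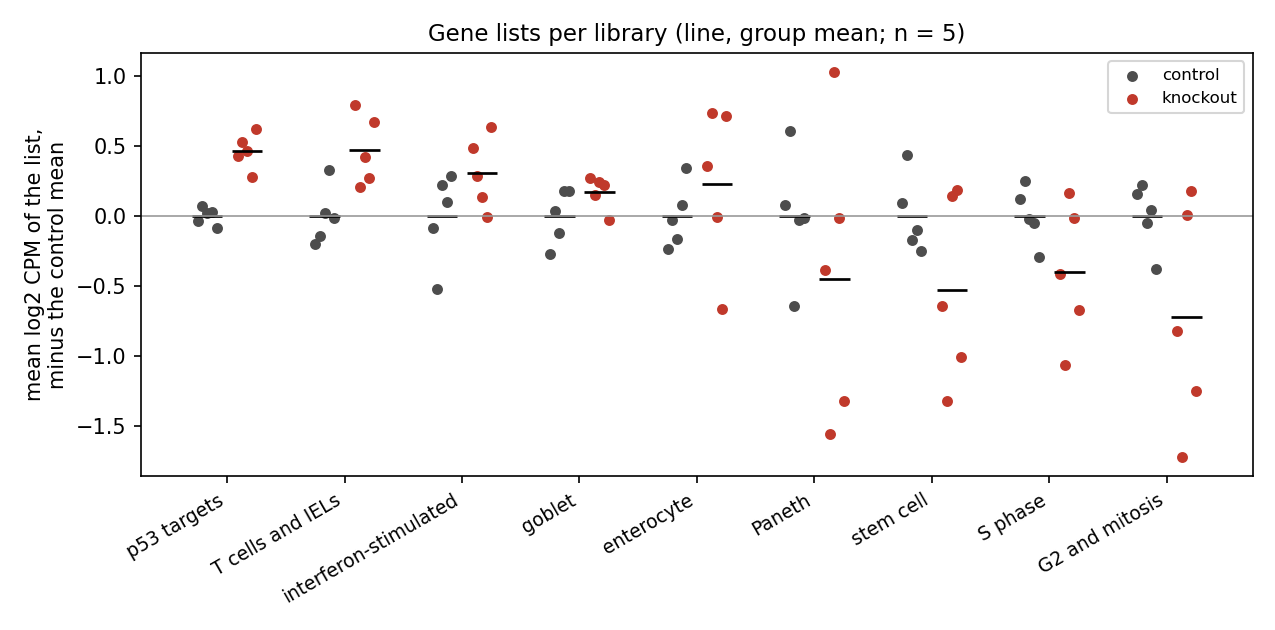
Mean log2 CPM of 9 gene lists per library, relative to the control mean. Points are the 5 libraries of each group and lines are group means; p53 targets lay above all controls in all 5 knockouts, while G2 and mitosis, stem cell and Paneth lists were spread widely among the knockouts.

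Interferon-stimulated genes and several stress and cell type lists passed camera with the preset correlation only. All 35 interferon-stimulated genes had positive values (median 0.34), with Irf7 at 0.42 (SE 0.18) and Parp14 at 0.20 (SE 0.13); 0 passed over all genes, and the camera adjusted p was 1.01e-07 (adjusted p = 0.545 with an estimated correlation). Goblet cell markers had a median of 0.14 (Zg16 0.66, SE 0.17, the 1 member higher when adjusted over the list alone; Fcgbp 0.13), with an adjusted p of 0.000294 (adjusted p = 0.545 with an estimated correlation). Unfolded protein response genes had a median of 0.19 (Hspa5 0.29, Calr 0.19), with an adjusted p of 0.00201 (adjusted p = 0.545 with an estimated correlation; 0.0595 without control replicate 1). For immediate early and heat shock genes the median was 0.24 (Fos 0.33, Hspa8 0.40) and the adjusted p 0.00201 (adjusted p = 0.64 with an estimated correlation), but the adjusted p was 0.0502 without control replicate 1 and 0.0913 without knockout replicate 5, and the median -0.021 with 1 surrogate variable. For antigen presentation the median was 0.13 (B2m 0.26, H2-K1 0.21) and the adjusted p 0.00489 (adjusted p = 0.688 with an estimated correlation), against 0.912 without control replicate 1, 0.0536 without knockout replicate 1 and 0.554 with the surrogate variable. Enterocyte markers had a median of 0.22 (Anpep 0.20, Fabp2 0.12) and an adjusted p of 0.00497 (adjusted p = 0.688 with an estimated correlation). The enterocyte call ended without control replicate 1 (0.0595), knockout replicate 2 (0.256) or knockout replicate 5 (0.193), and the surrogate variable turned the median to -0.14 (camera adjusted p = 3.34e-05). Mitochondrially encoded transcripts had a median of 0.09 (mt-Co1 0.04, mt-Cytb 0.08) and an adjusted p of 0.0407 (adjusted p = 0.688 with an estimated correlation). That call ended without control replicates 2 (0.182) or 5 (0.615, median -0.0040), without knockout replicates 1 (0.0769), 2 (0.201) or 4 (0.155), and with the surrogate variable (0.0507). Paneth cell markers had a median of -0.16 (Reg3b -0.06, Reg3g -0.07) and an adjusted p of 0.0146 (adjusted p = 0.688 with an estimated correlation). Their median turned to 0.036 without control replicate 2, 0.065 without knockout replicate 2, 0.045 without knockout replicate 5 and 0.27 with the surrogate variable, with adjusted p between 0.118 and 0.283. The T cell and lymphocyte markers, at a median of 0.48, differed between the same libraries.

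The list of the SETDB1 complex and other histone H3 lysine 9 regulators held Setdb1 itself, deleted by design, and was not tested without it. Its median was -0.10 (camera adjusted p = 0.0445, adjusted p = 0.688 with an estimated correlation). That call ended with upper-quartile factors (0.0525), without control replicates 1 (0.0897), 2 (0.134) or 3 (0.0593), without knockout replicates 1 (0.122), 2 (0.154) or 5 (0.193), and with the surrogate variable, where the median was 0.029. Beyond Setdb1, adjusted over the list alone, 2 were higher, among them Atf7ip, the cofactor that stabilises SETDB1 (63.9 ± 5.08 to 88.0 CPM, 0.46, SE 0.09; chosen after its values were seen), which lies on chromosome 6 at 136506167 to 136610862. The other lists had no camera call in the main fit. Their medians and adjusted p were 0.12 and 0.0768 for nucleic acid sensing (Ifih1 0.14, Tbk1 0.12), 0.24 and 0.0889 for regenerative markers (Krt19 -0.02, Krt7 0.0025), 0.12 and 0.0889 for tuft cells (Lrmp 0.24, Trpm5 0.22), and 0.33 and 0.118 for endothelium (Lyve1 0.33, Pecam1 0.50). For imprinted genes they were 0.05 and 0.191 (Igf2r 0.10, H13 0.03), for stroma 0.23 and 0.305 (Vim 0.37, Col3a1 0.34), for neurons and glia 0.17 and 0.305 (Ret 0.17, Snap25 0.19), and for enteroendocrine cells 0.04 and 0.305 (Chgb 0.04, Chga 0.02). They were -0.07 and 0.429 for ileal bile acid handling (Fabp6 -0.27, Cubn -0.23), 0.15 and 0.536 for germline genes (Xlr3a 0.33, Xlr4a 0.10), 0.08 and 0.597 for NF-kB genes (Ccl25 0.10, Nos2 0.15), 0.19 and 0.657 for clustered protocadherins (Pcdhgc3 0.03, Pcdhgc4 0.19) and 0.43 and 0.879 for red blood cells (Hbb-bs 0.54, Hba-a1 0.40). Median, mean and test direction disagreed in sign for cell death effectors (median 0.06, mean -0.02, up, adjusted p = 0.305; Gsdmd 0.16, Mcl1 0.08), for zinc finger genes (median 0.0046, mean -0.0079, up, 0.997), and for lineage regulators (median 0.02, mean 0.02, down, 0.997; Hnf4a -0.09, Maf -0.20). Of 34 lists 16 passed camera with a preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 1 by the directional fry test. By fry's mixed test 3 lists passed: macrophage, neutrophil and mast cell markers (adjusted p = 1.2e-05), p53 targets (1.41e-05) and the SETDB1 list (0.0126).

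The libraries were compared for technical differences. Mitochondrial genes took 5.10 ± 1.65% of counts in controls and 5.19 ± 0.47% in knockouts (SD, n = 5 per group, exact two-sided permutation p = 0.921), and the 50 most abundant genes 19.13 ± 0.69% and 20.3 ± 2.09% (exact permutation p = 0.254). The exact permutation p was 0.373 for total counts and 0.246 for the number of genes detected. The first principal component held 37.9% of the variance and placed knockout replicates 1, 2 and 5 at 22.6, 47.4 and 42.5, replicates 3 and 4 at -10.5 and -29.1, and the controls between -34.7 and -0.12 (exact permutation p = 0.119). Xist, the transcript that silences an X chromosome in female cells, and Y-linked genes showed both sexes in the groups: control replicates 1 and 3 and knockout replicate 4 carried Y-linked transcripts, while knockout replicate 2 had 0.05 CPM of Xist and at most 0.05 CPM of each of Ddx3y, Eif2s3y, Kdm5d and Uty.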

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

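The tests of lymphocyte RNA, of Gapdh reads and of the place of the p53 targets were chosen after the result was seen. In 6 of 184 groups of 5 libraries the extreme library lay apart from the others by more than Dixon's 95% critical value of 0.71, and chance gives about 1 in 20. The gap, as a share of the group's range, was 0.735 for Setdb1 in knockout replicate 4 (23.9 CPM, next 17.8), 0.812 for Pianp in control replicate 1 (0.90 CPM, next 0.57), 0.721 for Top2a in control replicate 5 (73.0 CPM, next 96.7), 0.855 for Mcpt1 in control replicate 5 (13.04 CPM, next 7.40), 0.835 for Gm5154 in knockout replicate 5 (0.81 CPM, next 0.55) and 0.756 for Mdm2 in control replicate 1 (77.9 CPM, next 66.2).

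Chance is argued against for the total number of genes and for the number of higher genes, each taken as a whole, and not for the number of lists. The 2 lower genes include Setdb1, deleted by design, so their number is no test of chance. The splits do not test single genes, and the higher genes include Esr1 and the genes of distal chromosome 6. Of 100 splits of the 10 libraries, drawn from 126, only the real split (1) gave as many as 27 genes or 25 genes in a single direction, the highest others being 6 and 5. Since a split and its mirror are the same, the larger direction of each other split was counted: as many as the 2 lower genes came from 2 splits, the real one included, and the other had 5 genes in its larger direction. As many as 16 lists came from 27 splits, the highest other being 23.

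The genes that gather on distal chromosome 6, with Gm13394, may come from a chromosome segment of another mouse strain that travels with the transgene, or from lost silencing of a gene cluster. The test written beforehand asked for an excess of lower genes among the uncalled genes there, and missed its threshold (odds ratio 1.84, 95% interval 0.863 to 3.50, Fisher's exact p = 0.0781). That criterion counted a missed p as evidence against a segment, which was wrong since the interval holds both 1 and the ratio of 1.83 found for higher genes (Fisher's exact p = 0.0265); it was replaced by the interval after the result was seen, and segment and silencing cannot be told apart here. The ratio of Gm13394 to Gapdh varied more than that to 17.9% of other genes, which leaves open whether Gapdh reads were counted at Gm13394. The median of the 11 genes was 2.82, above the largest lymphocyte marker, Cd4, at 0.92, while the lowest of the 11 stood at 0.81. The 11 genes were picked for passing the test, many from low counts where only large changes pass. The comparison therefore cannot decide whether a general gain of lymphocytes took part, and a rare cell rich in Klri1 was not tested.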

How the results depend on the processing

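The settings with Xist as covariate and without distal chromosome 6, Esr1 and Gm13394 were chosen after seeing the data. Setdb1 kept its direction and its call in every setting that gave it a value. The number of genes, 27 (25 higher, 2 lower), stayed within 1.5 times under other scaling factors, voom, a CPM filter, the surrogate variable and the removal of abundant genes, except that 1 gene was lower with the CPM filter. It was 93 with DESeq2 (84 higher, 9 lower; 61 adjusted p were NA), 58 with voom and sample quality weights (48 and 10) and 42 without a filter on low counts (39 higher). Leaving out each library gave 24 to 46 genes, 22 to 38 higher and 2 to 8 lower, the highest of each without knockout replicate 4. With Xist as covariate 1 gene was lower, and without distal chromosome 6, Esr1 and Gm13394 11 genes passed, 9 higher: 13 of the 27 were left out, and Mbl2, Grm4 and Miga1 lost their calls. The number of lists, 16, was 0 with an estimated correlation and 1 by the directional fry test, and 12 to 17 with each library left out. Some lists gained a camera call. With the surrogate variable these were enteroendocrine cells (adjusted p = 0.00171), tuft cells (0.0188), protocadherins (0.0304), zinc finger genes (0.0304), endothelium (0.0367) and macrophage, neutrophil and mast cell markers (0.0391). Tuft cells reached 9.93e-06 by camera without knockout replicate 5, and stroma 0.00152 with Xist as covariate. Genes detected only in the knockout were 4 with looser limits and 2 to 3 with each library left out. The cause of changes of sign was not tested. With 1 surrogate variable these were Gsdmd -0.076, Mcl1 -0.041, Fabp2 -0.34, Anpep -0.12, Igf2r -0.018, Lyz2 0.16, Ccl25 -0.053, Tbk1 -0.011, Reg3g 0.0027, Krt19 0.048 and Cdkn1a -0.058, and the lists of cell death -0.022, immediate early genes -0.021, enterocytes -0.14, lineage regulators -0.042, Paneth cells 0.27 and SETDB1 partners 0.029. With voom they were Pcdhgc3 -0.0086 and Krt7 -0.014, and with quality weights Pcdhgc3 -0.14, Chga -0.016, H13 -0.050, Krt7 -0.045, enteroendocrine markers -0.0090 and zinc finger genes -0.0043. Krt7 also turned to -0.00022 with DESeq2 size factors, -0.00020 with DESeq2, -0.0032 without a filter and -0.0021 without distal chromosome 6, where zinc finger genes turned to -0.00059. With Xist as covariate they were Fabp2 -0.043, Krt19 0.040, lineage regulators -0.040 and Paneth cells 0.038. With each library left out the ranges were Hba-a1 -0.11 to 0.63, Pcdhgc3 -0.11 to 0.15, Pcdhgc4 -0.0021 to 0.30, Fabp2 -0.027 to 0.29, Chgb -0.058 to 0.10, Chga -0.036 to 0.065, Xlr3a -0.024 to 0.57, Xlr4a -0.0098 to 0.23, H13 -0.0074 to 0.086, mt-Co1 -0.083 to 0.23, mt-Cytb -0.038 to 0.22, Nos2 -0.078 to 0.33, Reg3b -0.26 to 0.12, Reg3g -0.22 to 0.11, Krt19 -0.080 to 0.045 and Krt7 -0.081 to 0.076. For lists they were red blood cells -0.17 to 0.68, protocadherins -0.0021 to 0.30, endothelium -0.056 to 0.38, enteroendocrine cells -0.061 to 0.10, lineage regulators -0.029 to 0.058, mitochondrial transcripts -0.0040 to 0.27, neurons and glia -0.042 to 0.19, NF-kB genes -0.043 to 0.10, Paneth cells -0.81 to 0.065 and zinc finger genes -0.029 to 0.029. No paired analysis was possible because the replicate numbers of the columns are not tied to labelled samples and no label pairs the mice. The planned sex covariate was not run, since 1 library had neither Xist nor Y-linked transcripts. The depth limits calls near 1 CPM, where genes such as Eda2r rest on few counts.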

Other observations

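The test of the chromosome 6 segment for the p53 targets was chosen after the result was seen. The rise of p53 targets may follow the loss of Setdb1 or the activity of CreERT2, which cuts DNA. There were 0 libraries with CreERT2 and intact Setdb1, so CreERT2 activity and loss of Setdb1 cannot be told apart. A shift in cell composition along the main axis of variation is argued against as the whole cause. Knockout replicates 3 and 4 lay among the controls on the first principal component (-10.5 and -29.1). Their p53 list still stood at 0.46 and 0.28 relative to the control mean, against at most 0.07 in the controls. These means include the 4 called targets, which were picked for differing between the groups. Among the knockouts Ccng1 followed the order of that component, from 206 CPM in replicate 2 to 122 in replicate 4. The highest control had 80.9 CPM. Plk2 was also lowest in replicates 3 and 4, while Phlda3 and Eda2r did not follow the order. Part of the rise may thus go with that axis, and replicate 4 also kept the most Setdb1. With 1 surrogate variable 4 of 4 called targets passed, in a setting that moved the number of genes from 27 to 35 with 26 shared. The surrogate variable was estimated with the group in the model, so it cannot remove a shift in composition that follows the genotype. The chromosome 6 segment stays open: 0 of the 4 lie there, but few genes do, and a segment could act on genes elsewhere.

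Knockout replicate 2, with neither Xist nor Y-linked transcripts, may come from a mouse with a single X chromosome. The mean log2 CPM of 4 genes that escape X inactivation was 5.87 in it, within the 5.83 to 5.89 of the libraries with Y-linked transcripts and below the 6.38 or more of those with Xist. Loss of Xist with a reactivated second X chromosome is argued against, since X-linked genes stood at a median of -0.0649 relative to the other libraries, the lowest of the 10. Other explanations, a sample mix-up among them, were not tested.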
